A study of Coturnix japonica with 24 samples.

How the data were processed

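RNA from the liver and the abdominal white adipose tissue of male Japanese quail was sequenced as PCR-amplified cDNA on a Nanopore GridION, with 24 libraries in 6 groups of 4, per the labels. Each of the 2 tissues has 3 photoperiod groups, which the labels call 8L, 12v and 16v for 8, 12 and 16 hours of light. The deposited tables, 1 per tissue, hold expected counts (estimated counts of reads per transcript) for each library, with no normalization across libraries. Per the submitters' processing notes the reads were aligned with minimap2 and quantified with Salmon, for which the notes give no version. The genome build and annotation behind the counts are not given in the sources used here. The liver table lists 46968 transcripts of 14983 genes and the one for adipose tissue lists 51835 transcripts of 15542 genes. Of the genes, 11683 in liver and 12241 in adipose tissue carry a symbol and the others only a locus number. The quail RefSeq table holds 9932 and 10461 of those symbols, and it holds 0 of the transcript accessions.

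In the deposited values 99.49% (liver) and 99.56% (adipose tissue) are whole within 1e-06. A read that fits several transcripts of a gene appears to be counted on each of them. A gene's summed count was 1.84 times its largest transcript's count at the median in liver and 1.98 times in adipose tissue. Gene counts were the sum of a gene's transcript counts, each rounded to a whole number. An alternative, chosen after the data were seen, let the transcript with the highest mean CPM (the count scaled to a common library size) stand for its gene. In both ways of counting, loci with near-identical counts entered as separate genes. CPM values in the text use the library total scaled by trimmed mean of M values (TMM) factors. Floors of 3 counts for a group with no counts, like all counting limits here, cover counting error only, since PCR reads without molecular identifiers are not independent molecules. Total counts ran from 72125 to 867217 per library in liver and from 72716 to 1389063 in adipose tissue.

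Each tissue's 12 libraries entered a single edgeR quasi-likelihood fit with a mean per photoperiod (robust dispersion, 9 residual degrees of freedom). The fit used genes kept by filterByExpr (minimum count 10, minimum total 15), which left 4532 genes in liver and 6494 in adipose tissue. The 3 pairwise contrasts and an F test of any difference among the photoperiods were adjusted over all tested genes by Benjamini-Hochberg, with a threshold of 0.05. The adjusted p values of genes in the text are from this edgeR test unless another tool is named. The difference between tissues in a contrast was tested in an edgeR fit of all 24 libraries over 7107 genes. Standard errors (SE) of log2 fold changes were approximated as the size of the fold change over the square root of F. Software was R 4.3.3 with edgeR 4.0.16, limma 3.58.1 and DESeq2 1.42.0, and Python 3.11.15 with matplotlib 3.10.9 for the figures.

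Before the data were examined, 37 lists of genes for metabolic pathways, hormone axes, stress responses and cell types were fixed, with a panel of 12 genes per tissue. Lists with at least 5 measured members were tested with limma camera on voom values at a preset correlation of 0.01, adjusted over all lists and the 3 contrasts of a tissue. Camera with an estimated correlation and fry were run beside it. A list score is the mean of its members' log2 CPM (prior count 2), each centred over the 12 libraries. The ribosomal protein score is the first principal component of 70 ribosomal protein genes in a tissue. Genes named in the text followed a rule fixed at the same time. It took the 6 higher and 6 lower genes with a symbol and the smallest adjusted p under the threshold, up to 3 such members of each list, and the panel whatever its p. Where no gene passed, it took the 3 higher and 3 lower genes with the smallest p, as values only. Other list members are named where their list passed; these members were chosen after their values were seen.

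The alternatives fixed before the data were examined were relative log expression (RLE) factors, library size alone, no count filter, a stricter filter (a mean of at least 20 counts per library), limma-voom and DESeq2. They also included the replicate number as a block, fits of the 2 groups compared alone, transcripts tested singly, and each library left out in turn. Pseudocount alternatives were planned for normalized values only and did not apply to counts. Alternatives added after the data were seen were 1 transcript per gene, the ribosomal protein score as a covariate, both together, and leaving out 3 liver libraries. Further fits, with the share of counts at 17 near-identical loci as a covariate and on subsets of the genes, were also added then.

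The tests were tested on simulated data drawn to the depths and spreads of these tables, with 200 changed genes and the contrast of 16v with 8L. Each gene was drawn independently of the others, with no gradient between libraries. Within a tissue the changed genes came from those kept with 1 transcript per gene, so the shares recovered do not describe all genes tested. In liver, edgeR recovered 2.99% of the genes changed 2-fold, 29.9% of those changed 4-fold and 68.2% of those changed 8-fold, with 1 false call among 68. In adipose tissue the shares were 4.48%, 40.3% and 86.4%, with 3 false calls among 90. The tissue difference recovered 28.5% of 8-fold differences, with 3 false calls among 60. Camera gave p 1.66e-05 (liver) and 6.48e-08 (adipose tissue) for a list of 20 genes changed 1.5-fold, and 4 and 8 of 200 unchanged lists came out under 0.05. Those lists held independent genes, so they do not show how camera behaves where the genes of a list are correlated. All 24 libraries were used and none was left out of the reported values. Values of 3 of the genes that the rules above name or that belong to a list are not reported here, and counts of genes include them.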

Results

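Liver and abdominal white adipose tissue of male Japanese quail (Coturnix japonica) were profiled to describe how day length changes the expression of genes of energy metabolism. Birds from long days were held at 8 hours (8L), 12 hours (12v) or 16 hours (16v) of light, and each photoperiod gave 4 libraries of each tissue. Polyadenylated RNA was read as Nanopore PCR-cDNA, and each gene's expected count was the sum over its transcripts. Values are CPM (the count scaled to a common library size) as mean ± SD with n = 4 per group, and changes are log2 fold changes ± SE.

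Total counts of the liver libraries were 525035, 526837, 587059 and 696436 at 8L, 314488, 684240, 72125 and 642429 at 12v, and 460596, 810796, 674349 and 867217 at 16v. Those of the adipose libraries were 923031, 1389063, 351635 and 805120 at 8L, 465716, 786946, 301345 and 1350559 at 12v, and 543978, 72716, 667641 and 1148031 at 16v. ALB, the gene of serum albumin, took 7.86% of liver counts, and FABP4, which encodes the fatty acid binding protein of adipocytes, took 2.8% of adipose counts. The genes of cytosolic ribosomal proteins set 3 liver libraries apart. Their score was 7.13 in 12v replicate 1, 8.23 in 12v replicate 3 and 9.32 in 16v replicate 1, against -6.35 to 0.92 in the other liver libraries, with all of 8L at the low end (-6.35 to -3.38). In adipose tissue the score was -11.28 in 16v replicate 2, the library with 72716 counts. A set of 17 loci that carry a locus number only and near-identical counts took 10.1% to 18.8% of counts in 3 of the 8L liver libraries and 14.1% in 12v replicate 4. Their share was at most 3.01% in the other liver libraries and 3.15% to 26.5% in adipose tissue. Each of the 17 loci took 0.341% to 0.355% of all liver counts, so the same reads may be counted at each of them. These are shares of counts, and the share of reads would then be smaller.

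**Figure D1:**
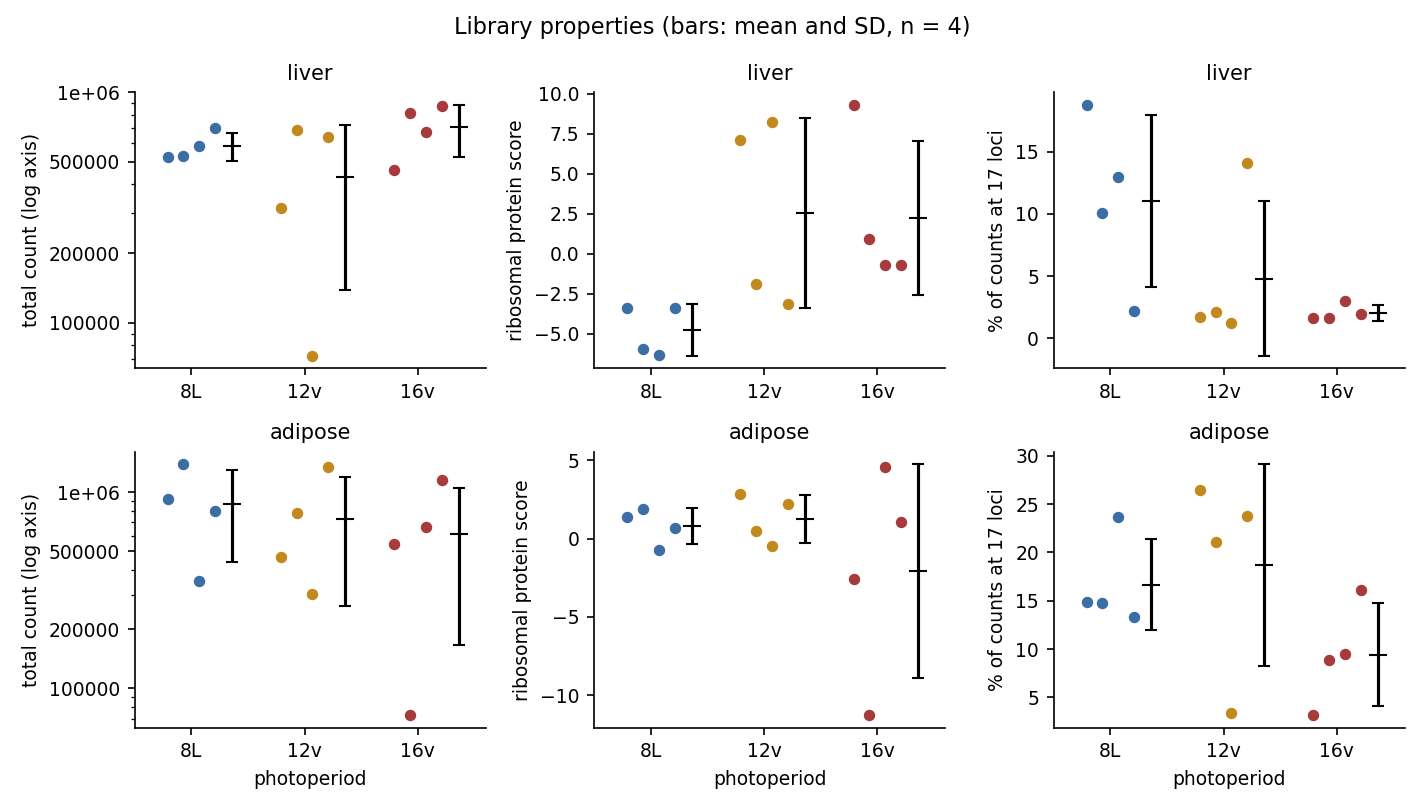
Total count (log axis), ribosomal protein score (first principal component of the ribosomal protein genes) and percent of counts at 17 near-identical loci in each library, by photoperiod, for liver and adipose tissue. Points are libraries and bars the mean and SD of 4; the liver scores at 8L lie between -6.35 and -3.38, and liver 12v replicate 4 has 14.1% of its counts at the 17 loci.

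The first comparison asks what differs in the liver between 12 and 8 hours of light. Genes that passed the threshold lower at 12v included FABP7 and PLIN2, which handle fatty acids and lipid droplets, and the glycolytic gene LDHA. FABP7, a fatty acid binding protein, fell from 738 ± 279 CPM at 8L to 99.1 ± 18.1 at 12v, a log2 change of -2.90 ± 0.38 (adjusted p = 0.00951). PLIN2, which coats lipid droplets, fell from 360 ± 106 to 76.4 ± 31.3 (-2.22 ± 0.40, adjusted p = 0.0392). LDHA, the lactate dehydrogenase subunit of glycolytic tissues, fell from 944 ± 685 to 66.6 ± 10.4 (-3.82 ± 0.63, adjusted p = 0.0355).

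S100A10, the partner of annexin A2, fell from 1010 ± 110 to 168 ± 54.9 CPM (-2.57 ± 0.47, adjusted p = 0.0392), with its reads also counted at the locus LOC121107546. EPAS1, which encodes the hypoxia-inducible factor HIF-2alpha, rose from 255 ± 111 to 1340 ± 628 (2.38 ± 0.41, adjusted p = 0.0355). SIRT4, a mitochondrial sirtuin, rose from 57.3 ± 37 to 460 ± 148 (3.00 ± 0.51, adjusted p = 0.0355). SELENOP1, the gene of selenoprotein P, rose from 410 ± 93.6 to 1390 ± 311 (1.76 ± 0.30, adjusted p = 0.0355), and CCDC152 from 384 ± 94.1 to 1810 ± 611 (2.23 ± 0.34, adjusted p = 0.0236). Each of these genes had all 4 of the 12v libraries outside the range of the 8L libraries. SCUBE1 was also higher and BIN1 lower past the threshold (adjusted p = 0.0392 and 0.00951), from few reads. Their largest transcripts held 34 and 19 counts over all 12 libraries, and BIN1 counted each read on about 36.8 transcripts.

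The lipogenesis list passed camera at 12v at its preset correlation (adjusted p = 0.00163) but not with an estimated correlation (adjusted p = 0.712). Its score was lowest in 12v replicates 1 and 3 (-0.84 and -1.41), where the ribosomal protein score was 7.13 and 8.23 and the hepatocyte marker score -0.75 and -0.94. Of the list's 22 measured members, 18 had a log2 change below 0 (median -1.07), 0 passed the threshold over all genes, and 9 passed, all lower, when adjusted over the list alone. THRSP, a regulator of lipogenic genes under thyroid hormone, averaged 6930 ± 2100 CPM at 8L and 710 ± 528 at 12v (-3.27 ± 0.64, adjusted p = 0.0531). FASN, the fatty acid synthase, averaged 2170 ± 664 and 557 ± 305 (-1.95 ± 0.48, adjusted p = 0.0776). SCD, the stearoyl-CoA desaturase, had -3.48 ± 0.91 (adjusted p = 0.0985) and ME1, malic enzyme, -2.41 ± 0.66 (0.118). ACLY, ATP citrate lyase, had -3.30 ± 1.03 (adjusted p = 0.145) and ACACA, acetyl-CoA carboxylase, -0.87 ± 0.44 (0.314). The cholesterol synthesis list had 13 of 14 members below 0 (median -1.14, camera adjusted p = 0.00299; adjusted p = 0.712 with an estimated correlation). It had 0 members past the threshold over all genes and 6, all lower, adjusted over the list alone. DHCR7, which makes the last step to cholesterol, had -3.27 ± 0.88, and MSMO1, a sterol methyl oxidase, -1.36 ± 0.35 (adjusted p = 0.108 and 0.0942).

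Glycolysis genes were below 0 in 8 of 9 members (median -0.98), with LDHA past the threshold over all genes and 4 members lower when adjusted over the list alone. TPI1, triose phosphate isomerase, had -1.99 ± 0.62 and GAPDH -2.18 ± 0.77 (adjusted p = 0.145 and 0.189). The list's camera adjusted p was 0.0252, adjusted p = 0.712 with an estimated correlation, and 0.0527 without 8L replicate 2. Hepatocyte markers were below 0 in 19 of 22 members (median -0.52, 0 past the threshold over all genes and 0 adjusted over the list alone), with camera adjusted p = 0.0224, adjusted p = 0.773 with an estimated correlation and 0.0775 without 8L replicate 3. Genes of the cytosolic ribosome were below 0 in 53 of 70 members (median -0.36, camera adjusted p = 0.00422; adjusted p = 0.773 with an estimated correlation), with 0 past the threshold over all genes and 5, all lower, adjusted over the list alone. Nuclear-encoded respiratory chain genes were below 0 in 48 of 71 members (median -0.47, camera adjusted p = 0.0115; adjusted p = 0.773 with an estimated correlation), with 0 past the threshold over all genes and 0 adjusted over the list alone. The respiratory chain list had adjusted p = 0.0775 without 8L replicate 3 and 0.0641 without 12v replicate 3. These lists moved alongside the ribosomal protein score, which lay at 7.13 and 8.23 in 12v replicates 1 and 3 and at -1.92 and -3.17 in 12v replicates 2 and 4. That score is drawn from the genes of the ribosome list, so for that list the link is no separate observation.

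**Figure D2:**
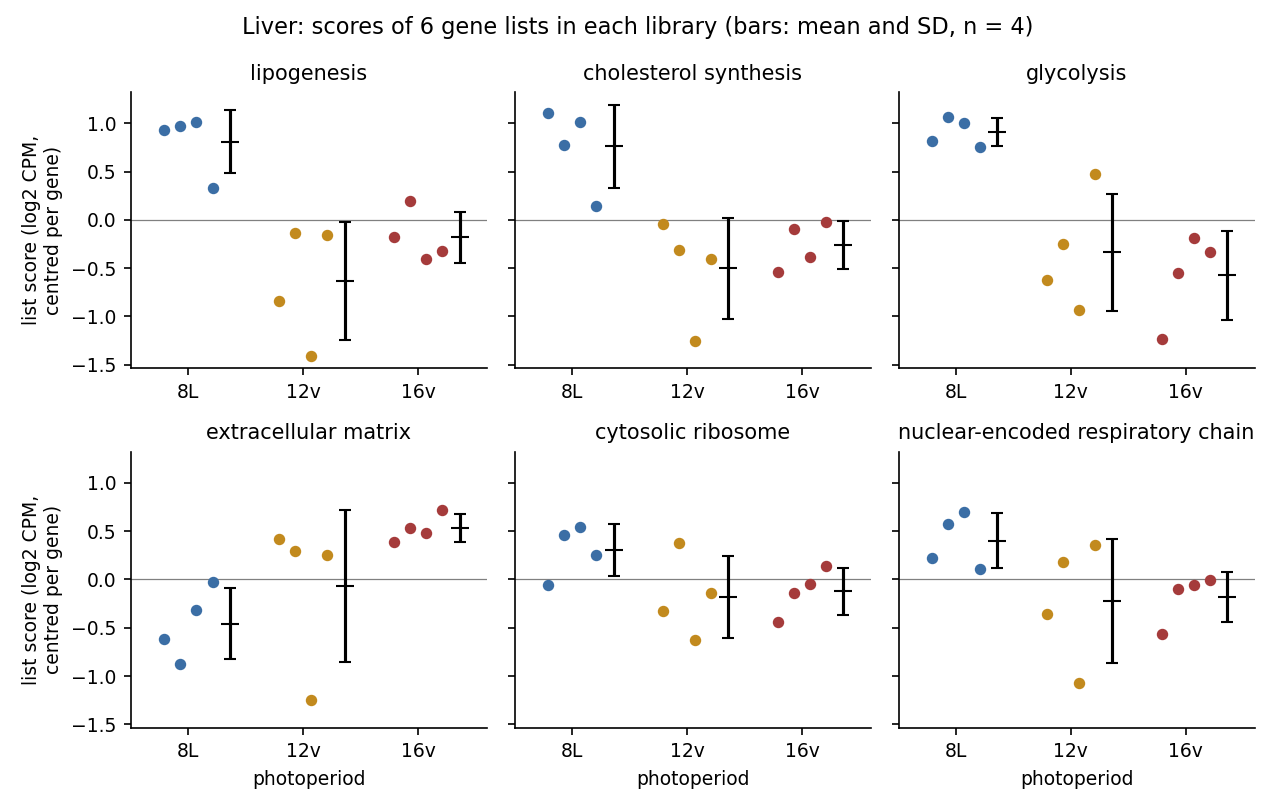
Scores of 6 gene lists (mean log2 CPM of the members, centred per gene over the 12 liver libraries) in each liver library, by photoperiod. Points are libraries and bars the mean and SD of 4; the lipogenesis score lies between 0.33 and 1.01 at 8L, between -1.41 and -0.14 at 12v and between -0.41 and 0.19 at 16v.

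Of the panel genes of the liver, CPT1A, which admits fatty acids to mitochondria, had a log2 change of 0.28 ± 0.99 at 12v against 8L. DIO1, a deiodinase that activates thyroid hormone, had 0.19 ± 0.52, GHR, the growth hormone receptor, -0.55 ± 0.58, PCK1, the gluconeogenic carboxykinase, -0.22 ± 1.13 and APOB, the apolipoprotein of very low density lipoprotein, 0.78 ± 0.26. Their adjusted p values were 0.908, 0.878, 0.633, 0.934 and 0.168. IGF1 and DIO3 had too few counts to test (means of 0.375 and 1.17 CPM at 12v). Leaving out single libraries turned the sign of CPT1A (-0.38 to 0.72), DIO1 (-0.18 to 0.47) and PCK1 (-1.55 to 1.63).

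In all, edgeR called 15 of 4532 genes at 12v against 8L, 9 higher and 6 lower, and 831 genes had an unadjusted p under 0.05. The share of calls that were higher was 60% with TMM factors, 46.7% with RLE factors and 83.6% with library size alone. The count was 6, 2, 2 and 4 without 8L replicates 1, 2, 3 and 4, 0, 0, 3 and 292 without 12v replicates 1, 2, 3 and 4, and 5 and 3 without 16v replicates 3 and 4. It was 3 with the ribosomal protein score as a covariate, 1 without the 3 libraries that score sets apart, and 141 with 1 transcript per gene, which included all 12 of the 15 that could be tested that way. Without those 3 libraries the 12v group kept replicates 2 and 4 only, so that fall cannot be told apart from the loss of libraries.

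At 16 hours of light, the question was again how the liver differed from 8 hours. Genes that passed the threshold lower included THRSP of lipid synthesis, CIDEC of lipid droplets and LDHA of glycolysis, and those higher included APOB of lipoproteins and the transcription factor EPAS1. THRSP fell from 6930 ± 2100 CPM at 8L to 585 ± 332 at 16v, a log2 change of -3.56 ± 0.65 (adjusted p = 0.0258). CIDEC, which promotes lipid droplet growth, fell from 114 ± 55.2 to 4.28 ± 2.44 (-4.63 ± 0.82, adjusted p = 0.0241). FABP7 fell from 738 ± 279 to 116 ± 42.7 (-2.67 ± 0.37, adjusted p = 0.0175) and LDHA from 944 ± 685 to 82.9 ± 38.4 (-3.51 ± 0.61, adjusted p = 0.0241).

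LEAP2, a liver peptide that opposes ghrelin at its receptor, fell from 473 ± 164 to 44.3 ± 19.5 CPM (-3.40 ± 0.59, adjusted p = 0.0241). PEMT, which makes phosphatidylcholine, fell from 294 ± 68.5 to 26.3 ± 9.03 (-3.46 ± 0.61, adjusted p = 0.0241). The glycogen genes PHKG1, a catalytic subunit of phosphorylase kinase, and PGM1, phosphoglucomutase, fell by 2.61 ± 0.45 and by 2.25 ± 0.40 (adjusted p = 0.0241 for both). AHSG, the gene of the plasma protein fetuin-A, fell from 2200 ± 801 to 477 ± 131 (-2.21 ± 0.40, adjusted p = 0.0257). APOB rose from 560 ± 93.5 to 1540 ± 217 (1.46 ± 0.26, adjusted p = 0.0257) and AKR1D1, a reductase of bile acid synthesis, from 195 ± 74.6 to 1610 ± 1290 (3.04 ± 0.57, adjusted p = 0.0317). AKR1D1 was 3510 CPM in 16v replicate 1 and 639 to 1220 in the other 16v libraries, and without 16v replicate 1 its change was 2.32 (adjusted p = 0.0747). EPAS1 rose to 1460 ± 130 (2.52 ± 0.41) and CCDC152 to 1440 ± 298 (1.91 ± 0.34), both with adjusted p = 0.0241. TEX14 rose from 559 ± 110 to 1860 ± 226 (1.73 ± 0.29, adjusted p = 0.0241), with its reads also counted at 3 loci without a symbol. Each of these genes had all 4 of the 16v libraries outside the 8L range. SCUBE1 was higher past the threshold (adjusted p = 0.0241), with 34 counts on its largest transcript over the 12 libraries.

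**Figure D3:**
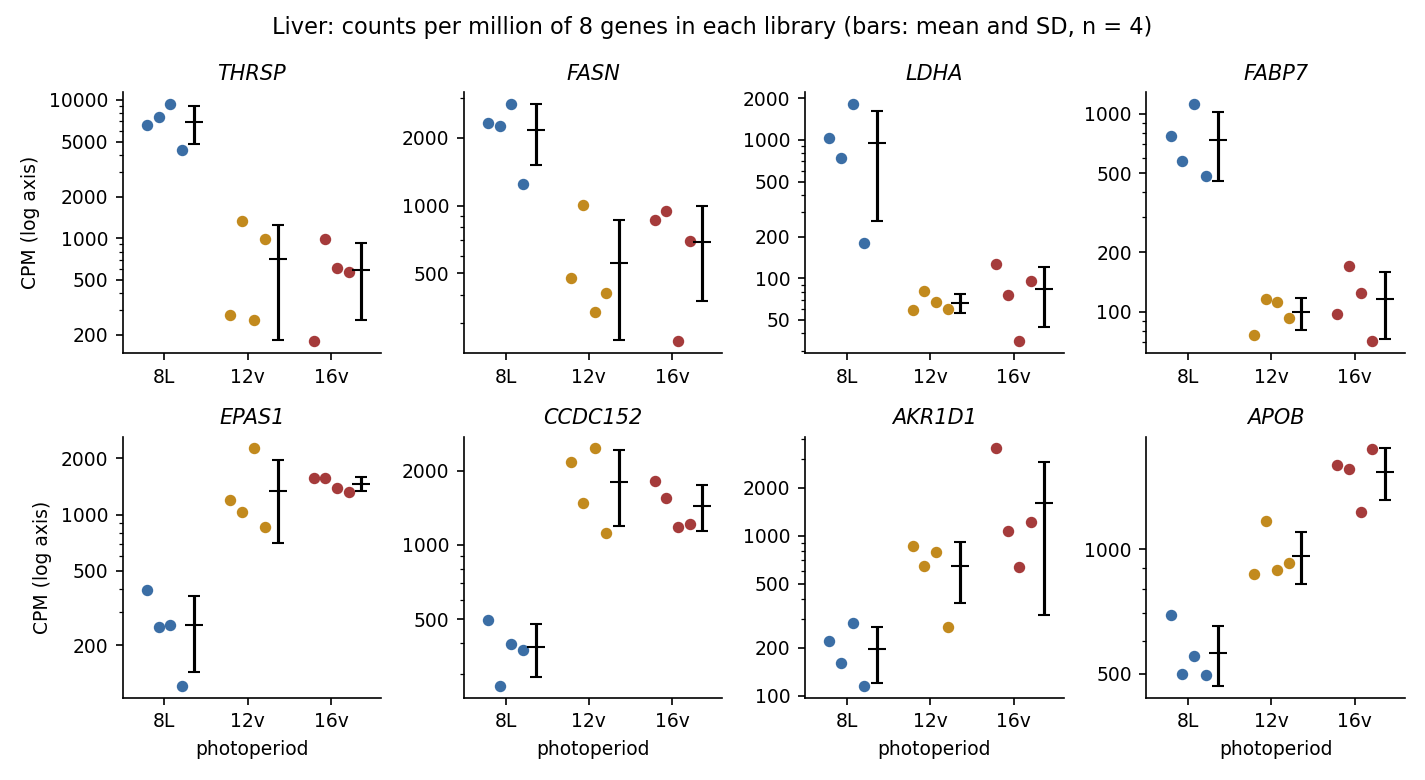
CPM (log axis) of 8 named genes in each liver library, by photoperiod. Points are libraries and bars the mean and SD of 4; THRSP averages 6930 at 8L, 710 at 12v and 585 at 16v, and APOB averages 560, 964 and 1540.

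The lipogenesis list had 16 of 22 members below 0 at 16v (median -0.85), with THRSP past the threshold over all genes and 5, all lower, adjusted over the list alone. Its camera adjusted p was 0.00439, with adjusted p = 0.712 with an estimated correlation. FASN averaged 688 ± 310 CPM (-1.66 ± 0.47, adjusted p = 0.0933), SCD had -2.94 ± 0.85 (0.096), ACLY -3.70 ± 1.04 (0.0922), ME1 -1.44 ± 0.64 (0.214) and ACACA -1.07 ± 0.44 (0.183). ELOVL5, an elongase of polyunsaturated fatty acids, had 0.69 ± 0.40 (0.344). Cholesterol synthesis genes were below 0 in 13 of 14 members (median -0.96, camera adjusted p = 0.00422; adjusted p = 0.712 with an estimated correlation), with 0 past the threshold over all genes and 3, all lower, adjusted over the list alone. All 9 glycolysis genes were below 0 (median -1.40, camera adjusted p = 0.00439; adjusted p = 0.712 with an estimated correlation), with LDHA past the threshold over all genes and 5 adjusted over the list alone. Of these, GAPDH had -2.78 ± 0.79 and TPI1 -2.08 ± 0.61 (adjusted p = 0.0924 and 0.099).

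Extracellular matrix genes were above 0 in 11 of 11 members (median 0.84, camera adjusted p = 0.0115; adjusted p = 0.712 with an estimated correlation), with 0 past the threshold over all genes and 0 adjusted over the list alone. COL4A1, a chain of basement membrane collagen, had 1.51 ± 0.55, COL3A1 0.90 ± 0.40 and FN1, fibronectin, 0.75 ± 0.34. Genes of the cytosolic ribosome were below 0 in 47 of 70 members (median -0.36, camera adjusted p = 0.00484; adjusted p = 0.773 with an estimated correlation), with 5 lower past the threshold over all genes and 9 adjusted over the list alone. RPS13, RPL36A and RPL21 fell by 1.72 ± 0.31, 1.61 ± 0.32 and 2.08 ± 0.42 (adjusted p = 0.0241, 0.0406 and 0.0431). Respiratory chain genes were below 0 in 49 of 71 members (median -0.54, camera adjusted p = 0.00299; adjusted p = 0.773 with an estimated correlation), with 0 past the threshold over all genes and 7, all lower, adjusted over the list alone. Hepatocyte markers were below 0 in 15 of 22 members (median -0.45, camera adjusted p = 0.0365; adjusted p = 0.773 with an estimated correlation), with AHSG past the threshold over all genes and 1 higher and 2 lower adjusted over the list alone. The hepatocyte call was lost without 8L replicate 2 (0.0736), 8L replicate 3 (0.122), 16v replicate 1 (0.178) or 16v replicate 2 (0.116). The ribosomal protein score moved with these groups: it was -6.35 to -3.38 at 8L and 9.32, 0.92, -0.71 and -0.69 in 16v replicates 1 to 4. Panel genes that did not pass were CPT1A (-0.13 ± 0.98, adjusted p = 0.961), DIO1 (0.34 ± 0.52, 0.74), GHR (-0.52 ± 0.56, 0.633) and PCK1 (0.27 ± 1.09, 0.919). The sign of CPT1A (-0.77 to 0.32) and PCK1 (-0.14 to 2.17) turned when single libraries were left out.

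In all, edgeR called 36 of 4532 genes at 16v against 8L, 17 higher and 19 lower, and 965 genes had an unadjusted p under 0.05. The share of calls that were higher was 47.2% with TMM factors, 36.4% with RLE factors and 76.1% with library size alone. The count was 3, 0, 0 and 13 without 8L replicates 1, 2, 3 and 4, 92, 15, 73 and 210 without 12v replicates 1, 2, 3 and 4, and 3, 3, 0 and 0 without 16v replicates 1, 2, 3 and 4. It was 2 with the ribosomal protein score as a covariate, 125 without the 3 libraries that score sets apart, and 478 with 1 transcript per gene, which included all 33 of the 36 that could be tested that way.

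Between the longer photoperiods, 16v and 12v, 1 liver gene passed the threshold. BIN1, a membrane-shaping protein, averaged 0.375 ± 0.751 CPM at 12v and 127 ± 70.2 at 16v and was that gene (adjusted p = 0.0198), with at most 1 count in a 12v library and 19 counts in all on its largest transcript. Of the lipogenic panel genes, THRSP averaged 710 ± 528 and 585 ± 332 CPM (-0.29 ± 0.59), FASN 557 ± 305 and 688 ± 310 (0.29 ± 0.46), ME1 292 ± 176 and 579 ± 465 (0.97 ± 0.64), SCD 9.74 ± 9.92 and 17.5 ± 15 (0.54 ± 0.89) and ACACA 421 ± 136 and 367 ± 123 (-0.21 ± 0.44), each with adjusted p = 0.999. APOB averaged 964 ± 137 and 1540 ± 217 (0.67 ± 0.26, adjusted p = 0.999), with all 4 of the 16v libraries above the 12v range. With edgeR 1 of 4532 genes passed and 90 had an unadjusted p under 0.05, and BIN1 was lost without any single 12v library, 16v replicate 2 or 16v replicate 3, each of which gave 0 calls. None of the 25 lists tested passed (0 by camera, 3 with unadjusted p under 0.05, 0 by fry), and camera called 2, 1, 1, 1 and 1 lists without 12v replicates 1, 2, 3 and 4 and 16v replicate 4. The test of any difference among the 3 photoperiods called 24 genes in liver (783 with unadjusted p under 0.05). That count was 6, 2, 2 and 4 without 8L replicates 1 to 4, 3, 14 and 221 without 12v replicates 1, 2 and 4, and 7, 4, 3 and 2 without 16v replicates 1 to 4.

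In adipose tissue, 1 gene passed the threshold at 12 hours of light against 8 hours. IGFBP2, which binds insulin-like growth factors, rose from 29.1 ± 14.4 CPM at 8L to 801 ± 399 at 12v, a log2 change of 4.83 ± 0.63 (adjusted p = 0.0237). Its level was 29.2, 10.9, 46.2 and 30.2 CPM in the 8L libraries and 1050, 322, 1200 and 634 in the 12v libraries. The adipose panel genes did not pass: FABP4 averaged 28000 ± 4480 and 32100 ± 10000 CPM (0.20 ± 0.37), ADIPOQ, adiponectin, had 0.10 ± 0.33, PLIN1, the perilipin of adipocytes, 0.08 ± 0.47 and PNPLA2, adipose triglyceride lipase, 0.01 ± 0.49, each with adjusted p = 1. LPL, lipoprotein lipase, averaged 1430 ± 470 and 672 ± 48.4 CPM (-1.09 ± 0.34, adjusted p = 0.61), and PPARG, the regulator of adipocyte formation, 483 ± 144 and 236 ± 53.3 (-1.04 ± 0.48, adjusted p = 0.975). In both, all 4 of the 12v libraries lay below the 8L range. The lipogenic panel had -1.21 ± 0.46 for FASN, -1.11 ± 0.57 for ME1, 0.24 ± 0.79 for SCD and 0.37 ± 0.56 for THRSP (adjusted p = 0.769, 1, 1 and 1). DIO2 and DIO3 had too few counts to test (8.1 ± 13.1 and 0.474 ± 0.576 CPM at 8L). The signs of ADIPOQ, PLIN1, PNPLA2 and SCD turned when single libraries were left out (-0.04 to 0.30, -0.23 to 0.27, -0.15 to 0.23 and -0.27 to 0.55).

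Immediate early genes were above 0 in 8 of 9 members at 12v (median 0.35, camera adjusted p = 0.00567; adjusted p = 0.901 with an estimated correlation), with 0 past the threshold over all genes and 1 adjusted over the list alone. That gene was CYR61, a matricellular protein induced by growth factors, with 3.16 ± 0.63 (adjusted p = 0.521 over all genes). Cholesterol synthesis genes were below 0 in 8 of 9 members (median -0.64) and erythrocyte markers above 0 in 5 of 6 (median 0.71), both with camera adjusted p = 0.0311 and adjusted p = 0.901 with an estimated correlation. Each had 0 members past the threshold over all genes and 0 adjusted over the list alone. The cholesterol call was lost without 8L replicate 2 (0.16), 8L replicate 4 (0.0869), 12v replicate 2 (0.0545) or 12v replicate 4 (0.108), and the erythrocyte call without 8L replicate 1 (0.0709), 8L replicate 2 (0.16), 12v replicate 1 (0.22) or 12v replicate 2 (0.12). The count of lists, 3 in all, was 1 without 8L replicate 2 and 6 without 8L replicate 3.

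In all, edgeR called 1 of 6494 genes at 12v against 8L in adipose tissue (324 with unadjusted p under 0.05), and 5 with 1 transcript per gene. The adjusted p of IGFBP2 was 0.22, 0.12, 0.0795 and 0.112 without 8L replicates 1, 2, 3 and 4, 0.0866, 0.0747 and 0.0668 without 12v replicates 1, 3 and 4, and 0.0536 and 0.0507 without 16v replicates 1 and 4, with a log2 change of 4.49 to 5.11 throughout.

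At 16 hours of light against 8 hours in adipose tissue, 3 lists passed camera at its preset correlation, 0 with an estimated correlation and 0 by fry. The list with the smallest p was that of the mitochondrial respiratory chain. Of its 71 measured members, 65 were above 0 with a median of 0.37 (camera adjusted p = 7.59e-10; adjusted p = 0.901 with an estimated correlation), 0 passed the threshold over all genes and 1 was higher adjusted over the list alone. That gene was NDUFB6, a subunit of complex I, with 1.98 ± 0.42 (adjusted p = 0.298 over all genes). Skeletal muscle markers stood alongside: all 14 were above 0 (median 4.31, camera adjusted p = 0.187), and they took 7.86% of counts in 16v replicate 4, 1.27% in 16v replicate 2, 1.22% in 12v replicate 2 and 0.536% or less in the other adipose libraries. These shares count a read on each transcript it fits, with TNNT3 alone at 4.46% in 16v replicate 4, and with 1 transcript per gene they were 3.25%, 0.564%, 0.443% and at most 0.157%. Extracellular matrix genes were below 0 in 21 of 26 members (median -0.34, camera adjusted p = 0.0152) and endothelial markers in 8 of 9 (median -0.89, camera adjusted p = 0.0311), both with adjusted p = 0.901 with an estimated correlation. Neither had a member past the threshold over all genes (0 and 0, and 0 and 0 adjusted over the list alone). COL3A1 had -1.48 ± 0.41 and COL4A1 -1.15 ± 0.38 (adjusted p = 0.466 and 0.527).

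**Figure D4:**
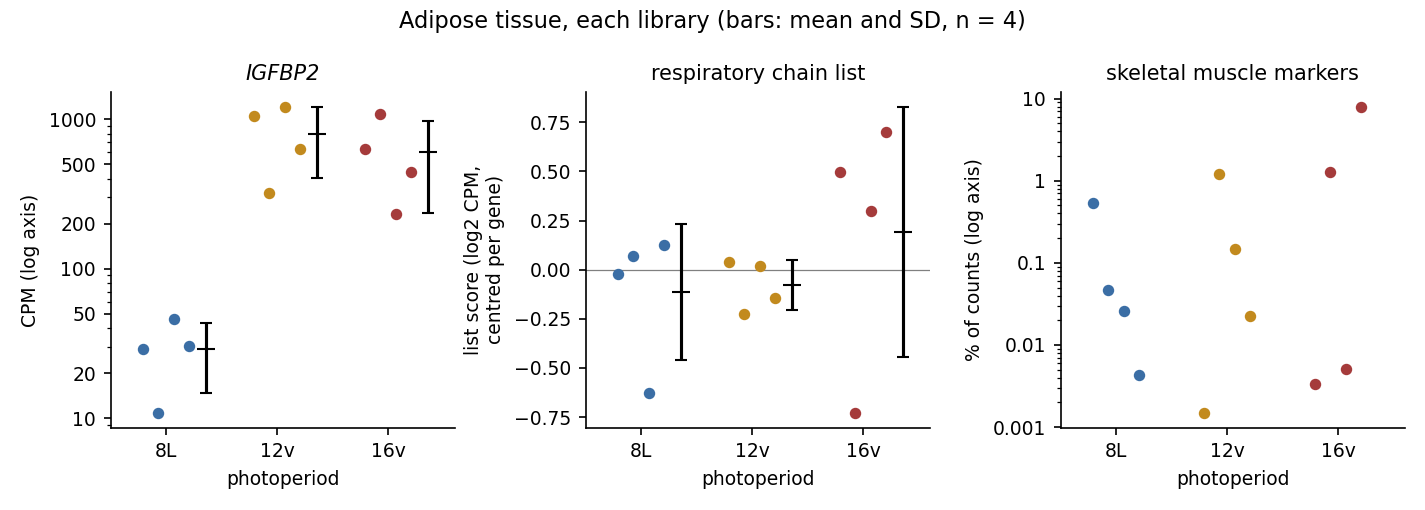
IGFBP2 CPM (log axis), respiratory chain list score (mean log2 CPM, centred per gene) and percent of counts from skeletal muscle markers (log axis) in each adipose library, by photoperiod. Points are libraries and bars, where drawn, the mean and SD of 4; IGFBP2 lies between 10.9 and 46.2 CPM at 8L and between 231 and 1200 in the other groups, and muscle markers, summed over transcripts, reach 7.86% in 16v replicate 4.

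No single gene passed at 16v against 8L in adipose tissue, and genes with small p are given as values. IGFBP2 averaged 602 ± 368 CPM at 16v (4.40 ± 0.62, adjusted p = 0.0547), with all 4 libraries above the 8L range. ANXA1, annexin A1, averaged 496 ± 204 and 1700 ± 494 (1.77 ± 0.33), and ITPR3, a calcium channel of the endoplasmic reticulum, 40.2 ± 6.07 and 5.04 ± 3.74 (-2.65 ± 0.51). SLCO2B1, an organic anion transporter, averaged 88.9 ± 34.5 and 21.4 ± 8.92 (-1.92 ± 0.41) and ZBTB32 1.36 ± 1.27, from at most 1 count per 8L library, and 20.4 ± 15. The adjusted p values of these 4 genes were 0.269, 0.269, 0.298 and 0.269 in that order. Of the panel, ADIPOQ had -0.95 ± 0.34, PPARG -1.09 ± 0.48, PNPLA2 0.98 ± 0.50, SCD 1.10 ± 0.79, THRSP 0.68 ± 0.56, FASN -0.72 ± 0.45, LPL -0.07 ± 0.34, FABP4 0.04 ± 0.37, PLIN1 0.13 ± 0.47 and ME1 -0.22 ± 0.57, with adjusted p from 0.589 (ADIPOQ) to 0.997 (FABP4), none past the threshold. The signs of FABP4, LPL, ME1 and PLIN1 turned or reached 0 when single libraries were left out (-0.23 to 0.27, -0.30 to 0.14, -0.69 to 0.00 and -0.20 to 0.36).

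In all, edgeR called 0 of 6494 genes at 16v against 8L, with 439 at an unadjusted p under 0.05, while DESeq2 called 38, limma-voom 0, and edgeR with 1 transcript per gene 13. The edgeR count was 1, 1 and 4 without 12v replicate 2, 16v replicate 3 and 16v replicate 4. The respiratory chain list kept its call at the preset correlation without each library in turn (adjusted p up to 0.000365), and with an estimated correlation it had adjusted p = 0.901. The extracellular matrix call was lost without 8L replicate 4 (0.0869) or 16v replicate 3 (0.404), and the endothelial call without 8L replicate 3 (0.138), 8L replicate 4 (0.0598), 16v replicate 3 (0.0655) or 16v replicate 4 (0.105). The count of lists, 3 in all, was 1 without 8L replicate 4 and 5 without 16v replicate 1.

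Between 16v and 12v in adipose tissue, no single gene passed with edgeR, and 5 lists passed camera at its preset correlation, 0 with an estimated correlation and 0 by fry. Respiratory chain genes were above 0 in 68 of 71 members (median 0.42, camera adjusted p = 7.19e-13; adjusted p = 0.901 with an estimated correlation). Skeletal muscle markers stood alongside, with 14 of 14 above 0 (median 3.17, camera adjusted p = 0.205) and their highest share of counts in 16v replicate 4 (7.86%, or 3.25% with 1 transcript per gene). Genes of the cytosolic ribosome were below 0 in 63 of 70 members (median -0.23, camera adjusted p = 0.000147; adjusted p = 0.954 with an estimated correlation), alongside a ribosomal protein score of -11.28 in 16v replicate 2, without which the adjusted p was 0.756. That score is drawn from the same genes and is no separate observation. Gluconeogenesis genes were above 0 in 4 of 5 members (median 1.10, camera adjusted p = 0.00467; adjusted p = 0.901 with an estimated correlation). Smooth muscle markers were below 0 in 7 of 8 members (median -0.61; adjusted p = 0.901 with an estimated correlation) and extracellular matrix genes in 20 of 26 (median -0.30; adjusted p = 0.924 with an estimated correlation), both with camera adjusted p = 0.0311. In these 5 lists 0 members passed over all genes, and adjusted over the list alone 1 gluconeogenesis gene passed and 0 in the others.

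Among the genes with the smallest p between 16v and 12v, all with adjusted p = 0.991, were SLC1A6, a glutamate transporter (1.80 ± 0.38), SIRT4 (4.68 ± 1.17), HOXA3 (-2.81 ± 0.65), FBXL7 (-3.73 ± 0.88) and CADM1 (no counts at 12v, where 3 counts per library would be 5.74 CPM on average, and 70.3 ± 75.7 CPM at 16v). In all, edgeR called 0 of 6494 genes (304 with unadjusted p under 0.05), limma-voom 0 and DESeq2 5. The smooth muscle call was lost without 8L replicate 2 (0.05), 12v replicate 2 (0.121), 12v replicate 4 (0.0683) or 16v replicate 4 (0.178). The matrix call was lost without 8L replicate 2 (0.0508), 8L replicate 4 (0.0546), 12v replicate 2 (0.0545), 12v replicate 4 (0.107) or 16v replicate 3 (0.678). The count of lists, 5 in all, was 3 without 8L replicate 2, 3 without 12v replicate 4 and 8 without 16v replicate 1. The test of any difference among the 3 photoperiods called 0 genes in adipose tissue with edgeR (354 with unadjusted p under 0.05), 37 with DESeq2 and 1 with limma-voom, and edgeR called 1 without 16v replicate 3.

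The last comparison asked whether liver and adipose tissue differed in their change with photoperiod. At 12v against 8L, SIRT4 rose in liver (3.00 ± 0.51) and had -3.97 ± 1.15 in adipose tissue, a difference of 6.89 ± 1.21 (adjusted p = 0.0257) that rests on few counts, with 2.54, 0, 0 and 2.49 CPM in the 12v adipose libraries. S100A10 fell in liver (-2.57 ± 0.47) and had 1.06 ± 0.45 in adipose tissue (difference -3.58 ± 0.70, adjusted p = 0.0257). MAN1A1, a mannosidase of glycan trimming, rose in liver (1.84 ± 0.35) and had -0.69 ± 0.35 in adipose tissue (difference 2.47 ± 0.48, adjusted p = 0.0257). At 16v against 8L, EPAS1 rose in liver (2.52 ± 0.41) and had -0.61 ± 0.49 in adipose tissue (difference 3.35 ± 0.66, adjusted p = 0.0373). CIDEC fell in liver (-4.63 ± 0.82) and had 0.32 ± 0.42 in adipose tissue (difference -4.76 ± 0.90), and PHKG1 fell in liver (-2.61 ± 0.45) and had 0.81 ± 0.42 (difference -3.19 ± 0.65), both with adjusted p = 0.0373.

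In all, edgeR called 34 of 7107 genes for a tissue difference at 12v against 8L, 26 with the liver change above the adipose change and 8 below (769 with unadjusted p under 0.05), and 21 at 16v, 12 above and 9 below (1075). The count at 12v was 19, 0, 0, 0 and 0 without liver 8L replicates 1, 2, 3 and 4 and 12v replicate 1, and 105 without liver 12v replicate 4. It was 0 without adipose 8L replicates 1, 2 or 3 or adipose 12v replicates 1, 2 or 3, and 57 without adipose 16v replicate 2. The count at 16v was 1, 0, 0 and 38 without liver 8L replicates 1 to 4, and 60 and 38 without liver 12v replicates 3 and 4. It was 3, 0 and 0 without liver 16v replicates 1, 2 and 4, 0 without adipose 8L replicates 1, 2 or 3 or adipose 16v replicate 1. It was 5 and 11 without adipose 12v replicates 1 and 4, and 33, 3 and 7 without adipose 16v replicates 2, 3 and 4.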

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

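The tests of explanations in this part were chosen only after the result to be explained was seen. For the tests on the 17 near-identical loci and on the gap between the 2 ways of counting, what each would show was written before its own value was seen.

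A library is given here when it lies further from the other 3 of its group than Dixon's test for 4 values allows. This held for 13 of the 141 groups of values examined, of which 11 are given here, and chance alone gives about 1 in 20. In liver at 8L, SCUBE1 was 1.47 CPM in replicate 4 and 0 in the others, and BIN1 was 299 in replicate 4 and 83.9 to 92.1 in the others. The value of SCUBE1 stands for 1 count. The lipogenesis score was 0.33 in 8L replicate 4, the lowest of the 8L libraries. In liver at 12v, the 17 near-identical loci took 14.1% of counts in replicate 4 and at most 2.11% in the others, BIN1 was 1.5 CPM in replicate 2 (1 count), and the extracellular matrix score was -1.249 in replicate 3. In liver at 16v, the ribosomal protein score was 9.32 in replicate 1, PLIN2 was 181 CPM in replicate 2 and 93.6 to 102 in the others, and the respiratory chain score was -0.563 in replicate 1. In adipose tissue, the 17 loci took 23.7% of counts in 8L replicate 3, and the immediate early score was 0.749 in 12v replicate 2 and 0.173 to 0.266 in the others. Liver 12v replicate 4 also had a ribosomal protein score of -3.17, near the 8L libraries (-6.35 to -3.38). Its first principal component over genes was -33.2, against -47.89 to -32.26 in the 8L libraries and -9.96 to 115.32 in the others. Genes past the threshold at 12v placed it with 12v: BIN1 was 0 CPM in it and 83.9 to 299 at 8L, CCDC152 1120 and 268 to 497, SIRT4 280 and 25.8 to 110, and FABP7 92.7 and 485 to 1120. These genes were chosen with this library in its group. Without it 292 genes passed at 12v against 8L, in place of 15, and whether its label is right was not tested and stays open. At 8L, replicate 4 had 2.19% of counts at the 17 loci and a score of -3.41.

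Other results stand here because the change with photoperiod differed between the tissues. At 12v against 8L the difference, liver minus adipose on the log2 scale, was 6.89 for SIRT4, 2.47 for MAN1A1, 2.40 for NRP1, 4.53 for MAPRE3, 2.44 for TEX14, -3.57 for GFPT1, -3.58 for S100A10, -6.35 for PPARD, -11.84 for EXD3, -7.43 for BIN1 and -3.35 for DUSP3. The adjusted p was 0.0463 for BIN1 and DUSP3 and 0.0257 for the other genes. At 16v against 8L, each with adjusted p = 0.0373, it was 3.35 for EPAS1, 6.15 for GAS6, 2.46 for NRP1, 2.42 for MAN1A1, 2.47 for TEX14, 8.12 for SCUBE1, -7.11 for GPD1L2, -4.76 for CIDEC, -3.59 for S100A10, -3.19 for PHKG1, -6.10 for UGT1A1 and -9.84 for PCBP2. The fitted differences of SIRT4, SCUBE1, BIN1, PPARD, EXD3, GAS6, GPD1L2, UGT1A1 and PCBP2 rest on groups or tissues with few counts, depend on the prior count and are no bounds. SIRT4 had 2.54, 0, 0 and 2.49 CPM in the 12v adipose libraries, and its difference was 5.59 with 1 transcript per gene. MAPRE3, TEX14 and S100A10 share their reads with loci that have no symbol.

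The liver genes past the threshold against 8L lie in groups that also differ in ribosomal protein score, in the share of the 17 loci and in depth. With the score as a covariate, 82% of the median size of the change at 16v was left in the gene sum (2.28 before, 1.87 after, median SE 0.42 and 0.44), all 36 genes kept their direction and 1 stayed past the threshold, the sizes being smaller and the SE larger. With 1 transcript per gene the covariate left 62.2% over the 478 genes that passed (1.95 and 1.21, SE 0.50 and 0.49), where 473 kept their direction and 77 stayed past the threshold, and 79.5% over the 33 that the gene sum also called (2.18 and 1.73, SE 0.41 and 0.42), of which 33 kept their direction and 30 stayed past it, so over all these genes the gradient between libraries and photoperiod cannot be told apart. Leaving out the smallest library, 12v replicate 3, left 94.4% of the change at 12v (2.55 and 2.41, SE 0.41 and 0.43). All 15 genes kept their direction and 3 stayed past the threshold. For these 15 genes, which were chosen with this library in the fit, that argues against it as the source of the size and direction. Most calls ended without it, so whether the calls rest on it stays open. The share of the 17 loci as a covariate left 91.9% at 16v (2.28 and 2.09, SE 0.42 and 0.50, 1 of 36 genes past the threshold). That share stays open, because the calls ended while the size and direction largely held, and photoperiod itself stays open.

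Respiratory chain genes lay above 0 in adipose tissue at 16v against 8L in 65 of 71 members (median 0.37, SE 0.07 if members were independent), with camera adjusted p = 7.59e-10 at its preset correlation, adjusted p = 0.901 with an estimated correlation, 0 members past the threshold and 0 lists by fry. At the preset correlation, the median was 0.51 without 16v replicate 2, the library with the fewest counts (67 of 72 above 0, camera adjusted p = 1.97e-17, and 0.901 with an estimated correlation and all libraries). That library had the lowest list score (-0.727), so leaving it out was bound to raise the median and is no test. With its low score it lowers the 16v group and is not the source of the rise. Without both 16v replicates with most muscle counts, 2 and 4, the median was 0.40 (62 of 72), which the loss of replicate 2 also raises. The list score of replicates 1 and 3, with 0.00331% and 0.00509% of counts from muscle markers, lay 0.51 above 8L (SE 0.20 between libraries). Part of that gap comes from 8L replicate 3, at -0.627 against -0.024 to 0.125 in the other 8L libraries. The lower of the 2 16v scores was 0.298, above all of 8L. In those 2 libraries of 16v this argues against muscle RNA as the whole source. Without 16v replicate 4 alone, where TNNT3 and ACTA1 reached 53000 and 6000 CPM in the gene sum and 2630 and 10500 with 1 transcript per gene and where 14 muscle markers could be tested, the median was 0.19 (53 of 72). That library had the highest list score of the 16v group (0.701), so leaving it out was bound to lower the median and is no test of muscle RNA. Replicate 2, with 1.27% of counts from muscle markers, had the lowest list score (-0.727). Whether muscle RNA adds to the difference stays open, and photoperiod stays open.

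More liver genes passed at 16v against 8L with 1 transcript per gene (478) than in the gene sum (36). Of the 478, 352 carry a symbol. The others include the 17 near-identical loci and a locus whose counts nearly match those of 34 others, each counted as a gene. Some genes have their reads counted once within the gene, so the 2 ways count them alike, though different loci may still share reads. Of these genes, 311 of 1408 passed with 1 transcript per gene and 16 of 1380 in the gene sum. That argues against repeated counting of a gene's own reads as the whole source. Repeated counting across loci was not tested. When the gene sum was fitted on only the 2586 genes also tested with 1 transcript, 389 passed, so the thinly counted genes that the gene sum adds to the fit are a candidate source of the gap. No biological explanation was tested for this gap.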

How the results depend on the processing

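The tests with 1 transcript per gene, with the ribosomal protein score as a covariate, with both, and without the 3 liver libraries that score sets apart were chosen only after the result was seen. Where no cause is given below, the cause was not tested. Without those 3 libraries the liver 12v group kept replicates 2 and 4 only. Lower counts at 12v in those fits cannot be told apart from the loss of libraries.

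In liver at 12v against 8L 15 genes passed. The count was 67 with library size alone, 43 with no count filter, 86 with a mean of at least 20 counts per library and 365 with DESeq2. It was 26 with the replicate number as a block, 5 with the 2 groups alone, 129 with each transcript tested singly and 141 with 1 transcript per gene. With the score as a covariate it was 3, with 1 transcript and the score 29, without the 3 libraries 1, and with 1 transcript and without them 30. At 16v against 8L (36 genes) it was 88, 52, 129, 546, 65, 298, 396, 478, 2, 108, 125 and 558 in the same order, and 221 with limma-voom. At 16v against 12v (1 gene) it was 3 with DESeq2 and 0 with limma-voom, the block, the 2 groups alone, transcripts singly, 1 transcript per gene (with and without the score) and without the 3 libraries. For any difference (24 genes) it was 50 with no filter, 72 with the stricter filter, 463 with DESeq2, 88 with limma-voom, 247 for transcripts, 198 with 1 transcript per gene, 2 with the score, 37 without the 3 libraries and 306 with 1 transcript and without them, and 36 with RLE factors. Leaving out single libraries gave 0 to 292, 0 to 210, 0 to 1 and 2 to 221 genes. The median of all genes moved to -0.157 with RLE factors at 12v and to 0.146 and 0.329 with library size alone at 12v and 16v.

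In adipose tissue at 12v against 8L (1 gene) the count was 22 with DESeq2, 0 with the block, 5 for transcripts, 5 with 1 transcript per gene and 33 with 1 transcript and the score. At 16v against 8L (0 genes) it was 1 with no filter, 1 with the stricter filter, 38 with DESeq2, 9 for transcripts, 13 with 1 transcript, 1 with the score and 24 with both. At 16v against 12v (0 genes) it was 5 with DESeq2. For any difference (0 genes) it was 1 with no filter, 37 with DESeq2, 1 with limma-voom, 4 for transcripts, 12 with 1 transcript, 1 with the score and 39 with both. Leaving out single libraries gave 0 to 1, 0 to 4, 0 to 0 and 0 to 1 genes.

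In liver 6, 7 and 0 lists passed at 12v against 8L, 16v against 8L and 16v against 12v. With an estimated correlation 0, 0 and 0 passed, with fry 2, 3 and 0, and with the score as a covariate 2 and 3. Without the 3 libraries 3 lists passed at 12v against 8L and 2 at 16v against 12v, and at 16v against 12v 1 passed with the block and 2 with 1 transcript per gene. In adipose tissue (3, 3 and 5 lists) 0, 0 and 0 passed with an estimated correlation and 0, 0 and 0 with fry, and 5 and 5 with the block at 12v and 16v against 8L. Leaving out single libraries gave 4 to 8, 6 to 8 and 0 to 2 lists in liver and 1 to 6, 1 to 5 and 3 to 8 in adipose tissue.

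The tissue difference at 12v against 8L (34 genes) was 64 with RLE factors, 73 with the stricter filter, 22 with the block, 69 with 1 transcript per gene and 0 without the 3 libraries. At 16v against 8L (21 genes) it was 45, 75, 4, 241 and 56 in the same order, and 72 with limma-voom and the bird as a block. Leaving out single libraries gave 0 to 105 and 0 to 60 genes.

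No named gene or list past the threshold turned its direction under any alternative run. Of the 25 named liver genes past the threshold at 16v against 8L, 25 stayed past it with DESeq2, library size alone, limma-voom, the 2 groups alone and without the 3 libraries, 24 of 24 with the stricter filter, 23 with RLE factors, 22 with the block, 17 with no filter and 1 with the score as a covariate. At 12v against 8L, of 12 named genes 12 stayed past it with DESeq2, 7 with limma-voom, 2 with the score and 1 without the 3 libraries. IGFBP2 in adipose tissue at 12v, fitted with all libraries, stayed past it with each alternative but the block (adjusted p 0.319). Without single libraries these named genes kept their direction in every fit, and 0 of them stayed past the threshold in every fit.

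Signs turned among genes that had not passed. In liver at 12v, GHR was 0.10 with the score, 0.14 with 1 transcript and the score, 0.02 without the 3 libraries and 0.06 with 1 transcript and without them. PCK1 was 0.07 with library size alone, 1.63 with limma-voom, 0.35 with the block, 0.04 with 1 transcript, 1.24 with the score, 1.06 with both, 0.54 without the 3 libraries and 0.63 with 1 transcript and without them. In liver at 16v, CPT1A was 0.17 with library size alone, 0.01 with 1 transcript, 1.55 with the score, 1.30 with both, 0.33 without the 3 libraries and 0.33 with 1 transcript and without them, and with the score alone and with both GHR was 0.32 and 0.29, CIDEA 0.17 and 0.08 and CYP3A5 0.44 and 1.41. In adipose tissue at 12v, PNPLA2 was -0.01 with library size alone, -0.01 with no filter, -0.06 with the block, -0.02 with the score and -0.01 with both. At 16v, FABP4 was -0.08 with limma-voom and -0.07 with the block, and LPL 0.12 with the score and 0.09 with both. Without single libraries, liver at 12v gave CPT1A -0.38 to 0.72, DIO1 -0.18 to 0.47 and PCK1 -1.55 to 1.63, liver at 16v gave CPT1A -0.77 to 0.32 and PCK1 -0.14 to 2.17, and SERPING1 at 16v against 12v was -7.93 to 0.00. In adipose tissue ADIPOQ (-0.04 to 0.30), PLIN1 (-0.23 to 0.27), PNPLA2 (-0.15 to 0.23) and SCD (-0.27 to 0.55) turned at 12v and FABP4 (-0.23 to 0.27), LPL (-0.30 to 0.14), ME1 (-0.69 to 0.00) and PLIN1 (-0.20 to 0.36) at 16v.

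Residuals of libraries with the same replicate number correlated at -0.17 to 0.215 in liver (3 of 12 pairs over 0.1) and -0.096 to 0.047 in adipose tissue (0 of 12), and those of the same bird across tissues at -0.044 to 0.071 (0 of 11), so the numbers were not used to pair libraries. On simulated data at these depths, with genes drawn independently, 29.9% of genes changed 4-fold were recovered in liver and 40.3% in adipose tissue.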

Other observations

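The counts over other splits of the libraries and the fits with 1 transcript per gene were tests chosen only after the result was seen.

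In liver at 16v against 8L, 36 genes passed, 1 of 35 splits of the 8 libraries gave as many (the real one), and the highest other split gave 1. A share of 1 of 35 is the lowest that 35 splits can give, and the shares were not adjusted for the number of such tests. Only the real split also gave as many with 1 transcript per gene (478 genes, 1 of 35, highest other 0). The same held for any difference among the photoperiods (24 genes, 1 of 100 splits sampled, highest other 1). At 12v against 8L, 15 genes passed, 2 of 35 splits gave as many and the highest other gave 23, so chance cannot be excluded. With 1 transcript per gene only the real split gave as many there (141 genes, 1 of 35, highest other 27). In both ways of counting that other split exchanges 8L replicate 4 with 12v replicate 4, whose label stays open above. For 16v against 12v chance cannot be excluded (1 gene, 2 of 35, highest other 1). With 1 transcript per gene 0 genes passed there, so 35 of 35 splits gave as many by construction, which says nothing about chance. The highest other split gave 223. That split sets 12v replicates 1, 2 and 3 with 16v replicate 1 against the rest and points to a structure of the samples that does not follow these photoperiods. For gene lists in liver chance cannot be excluded for the 6 lists at 12v against 8L (6 of 35 splits, highest other 10) or the 7 at 16v against 8L (7 of 35, highest other 11). At 16v against 12v 0 lists passed, so every split gave as many by construction (highest other 6).

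In adipose tissue chance cannot be excluded for 12v against 8L (1 gene, 5 of 35 splits, highest other 2). At 16v against 8L, at 16v against 12v and for any difference 0 genes passed, so every split gave as many by construction. Those comparisons say nothing about chance (highest other 1, 0 and 2). With 1 transcript per gene only the real split gave as many at 12v against 8L (5 genes, 1 of 35, highest other 2). Chance cannot be excluded that way at 16v against 8L (13 genes, 3 of 35, highest other 18). At 16v against 12v 0 genes passed that way, so the comparison is empty (highest other 18). For gene lists chance cannot be excluded at 12v against 8L (3 lists, 21 of 35, highest other 7), 16v against 8L (3 lists, 29 of 35, highest other 10) or 16v against 12v (5 lists, 14 of 35, highest other 7). For the difference between tissues only the real split gave as many at 12v against 8L (34 genes, 1 of 35, highest other 4) and at 16v against 8L (21 genes, 1 of 35, highest other 1).

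With 1 transcript per gene, more genes passed in liver in all. Of the 141 and 478 genes at 12v and 16v against 8L, 100 and 352 carry a symbol. The others include groups of loci with near-identical counts, each locus counted as a gene. Of 20 lipogenesis genes measured that way, 7 passed lower at 12v against 8L, and 1 passed higher and 5 lower at 16v against 8L. The 141 genes at 12v became 1, 1 and 65 without 8L replicates 2, 3 and 4, 4, 67, 60 and 686 without 12v replicates 1 to 4 and 412 without 16v replicate 1. The 478 at 16v became 90, 104 and 234 without 8L replicates 2, 3 and 4 and 265, 168 and 262 without 16v replicates 1, 2 and 4. At 12v against 8L, ACLY had a log2 change of -3.06 (adjusted p = 0.022), FASN -1.88 (0.0371), SCD -3.31 (0.0339), ME1 -2.33 (0.0477), ACACA -0.72 (0.264, not past the threshold), THRSP -3.21 (0.022) and DHCR7 -3.08 (0.022). At 16v against 8L, ACLY had -3.55 (0.012), FASN -1.54 (0.0402), SCD -2.80 (0.0226), ME1 -1.32 and ACACA -0.92 (0.119 and 0.126, not past the threshold), THRSP -3.46 (0.0122) and DHCR7 -2.36 (0.015), while ATF4, a stress response factor, had -2.45 (0.0143) and KLF9, a glucocorticoid and thyroid hormone responsive factor, 2.35 (0.0321). In adipose tissue, where single libraries left out gave 1 to 22 genes at 12v and 3 to 31 at 16v, IGFBP2 had 4.95 at 12v (0.000254) and 4.41 at 16v (0.00169), CYR61 3.32 at 12v (0.00198) and NDUFB6 2.01 at 16v (0.00581).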
